A study of Oryza sativa with 8 samples.

How the data were processed

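RNA from roots of a cold-tolerant and a cold-sensitive indica rice line was sequenced after growth at 28 °C or transfer to 10 °C. Per the labels, the 4 groups (tolerant and sensitive roots, each at 28 °C and at 10 °C) held 2 libraries each, 8 in all, with 4 plants per library. Libraries were made from poly-A RNA and read as single ends of 50 bp on a HiSeq 2000, per the labels' protocols. Grouping followed the labels, and nothing beyond the words "biological rep" says how the replicates were separated.

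The data used were the authors' 4 deposited comparison tables, each of which sets 1 group against another for 42189 gene IDs. Per the file headers, the columns are those of a DESeq2 results table, and the version of that tool is not given in the sources used here. The mean normalised signal per gene over all libraries was computed by the authors from counts divided by size factors, and it was identical in the 4 tables, so all libraries were in 1 fit. The log2 fold changes and their standard errors are the authors' deposited values. The score in each deposited table is the Wald statistic, the log2 fold change divided by its standard error. Each p-value and adjusted p-value is as deposited by the authors, the latter adjusted by Benjamini-Hochberg over the genes left by a filter on low means. The submitters' processing notes name Bowtie 0.12.7 as aligner. The name given to the deposited tables points to another aligner, STAR, and which of them made the values is not given in the sources used here. Genome build, annotation release, read counter and the treatment of reads that match several loci are not given in the sources used here either. Values per library were not used here, so no count test was refitted, no library was left out in turn, and no standard deviation between replicates is printed.

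Of the 42189 IDs, 42004 were rice locus IDs and 185 were others; 6354 had a mean of 0 and 35835 had a p-value. The fold changes of the 4 tables closed as a loop to within 7.59e-14. Genes seen as a single read in a single library gave the size factor of each of the 8 libraries and the direction of each table, in which a positive value means higher in the second-named group (8 of 8 libraries). Group levels were calculated from the mean over all libraries and the fold changes, as normalised read counts, and carry no standard deviation. Reads in a low group were the level times the summed size factors, rounded, and taken as 0 where well under 1 read. A gene whose lower group held 0 reads was given a fold of at least the level in the other group over a floor of 3 reads over the group. With 1 to 3 reads in the lower group, the ratio is given with its exact 95% Poisson counting interval. Intervals and floors cover counting error only. They leave out the spread between replicates, so a fold given as "at least" is no bound on that spread.

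Genes with an adjusted p below 0.05 in the authors' deposited table were counted per comparison, as planned before the data were examined for files of this kind. The difference between the cold responses of both lines was tested with a Wald test derived from the deposited tables: the difference of the log2 changes over the root of the summed squared standard errors, with a normal p and Benjamini-Hochberg adjustment over the 26199 genes tested in both responses. That test was added after the data were seen and departs from the design. The design had held it not possible from comparison tables alone and planned to give both responses side by side. Calls of both responses were set against the number expected if they were independent.

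Of 33 gene lists fixed before the data were examined, 10 held written loci and could be used: CBF/DREB and cold regulators, dehydrins and LEA proteins, trehalose metabolism, abscisic acid synthesis and breakdown, circadian clock, catalases, aquaporins, iron uptake and phytosiderophores, nitrate transport, and alcohol dehydrogenases. The other 23 were defined by product descriptions, which no source used here gives, and they had no member. Some of the 10 carry narrower names here than when fixed. The abscisic acid list was fixed with PP2C in its name, and catalases as reactive oxygen scavenging. Nitrate transport was fixed as nitrate and ammonium transport, and alcohol dehydrogenases as alcoholic fermentation and sucrose use. A further 5 lists were written after the data were seen: photosynthesis in shoots, jasmonate JAZ repressors, a wider aquaporin list, small heat shock proteins and ammonium transporters. The loci of all lists came from general knowledge of rice; 0 gene IDs could be matched to a name in the reference table, so no list membership was checked and no ID is given a gene name. All 58 loci of the fixed lists and 46 of the 47 added loci were in the tables. Lists with at least 5 tested members were tested with 2-sided Fisher's exact tests of called members against all other tested genes, per direction, adjusted by Benjamini-Hochberg over lists and directions, separately for fixed and added lists. The camera test of limma 3.58.1 was run on the Wald statistics with preset correlations of 0.01, 0.05 and 0.2; a correlation could not be estimated without values per library. Per comparison, the 2 largest rises and 2 largest falls among called genes above the median of mean expression are named by ID, and for the difference between responses the 2 lowest p-values per direction. The rule fixed beforehand asked for named products and took more genes; it was narrowed because no names were at hand.

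Positions along chromosomes were read from the locus numbers. Calls per chromosome were tested by a chi-square statistic with 100000 shuffles of the calls. Stretches rich in calls were windows of 50 tested loci with more calls than 95% of the highest windows in 1000 shuffles, joined where they overlapped. Neighbouring calls were counted as pairs against 1000 shuffles, and for the cold responses also among the 211 genes with the largest Wald statistics. The interval for the medians of rises and falls came from 2000 resamples of chromosomes. All tests by position were chosen after the data were seen.

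Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. On simulated data, the test of the difference called 18% of 50 genes with a true log2 difference of 1, 74% at 2, 96% at 4 and 100% at 6, and 0.0385% of unchanged genes. Errors were drawn as normal with the very standard errors that the test used, so a misjudged spread was not covered. All changed genes lay at or above the median of mean expression, so recovery below it was not measured. Of 10 planted stretches, with 10 calls in 50 loci each, 10 were found, whereas 6 calls in 50 loci made a real stretch. Alternatives tried were no filter on low means, a mean of at least 10, genes above the median of mean expression, a change of at least 2-fold, an adjusted p below 0.01, statistics rescaled by their robust spread, other preset correlations, and windows of 30 or 100 loci.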

Results

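The series sampled roots of 2 indica rice lines at about 30 days, when seedlings had 3 leaves. The labels call 1 of these IRGA breeding lines cold-tolerant and the other cold-sensitive, and the line names share a stem. Plants stayed at 28 °C or were moved to 10 °C, and each of the 4 groups gave 2 libraries of 4 plants each. The labels conflict on the time in the cold. The extraction protocol gives 24 h, while the treatment protocol and the titles and descriptions of the cold samples give up to 10 days. The hour of harvest is not given in the sources used here.

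Relative sequencing depth, as the size factor of each library, was lower in the cold, with size factors of 0.679 to 0.991 at 10 °C and 1.10 to 1.25 at 28 °C. The mean normalised counts of all genes summed to 19350909 per library, and the 10 most abundant genes took 3.49% of them. A group's level of 0 reads allowed up to 1.22 normalised counts in tolerant and 1.28 in sensitive roots at 28 °C, and 1.66 and 1.83 at 10 °C. Gene IDs could not be paired with names, so single genes are given by ID, and gene groups are lists of loci written from general knowledge.

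**Figure D1:**
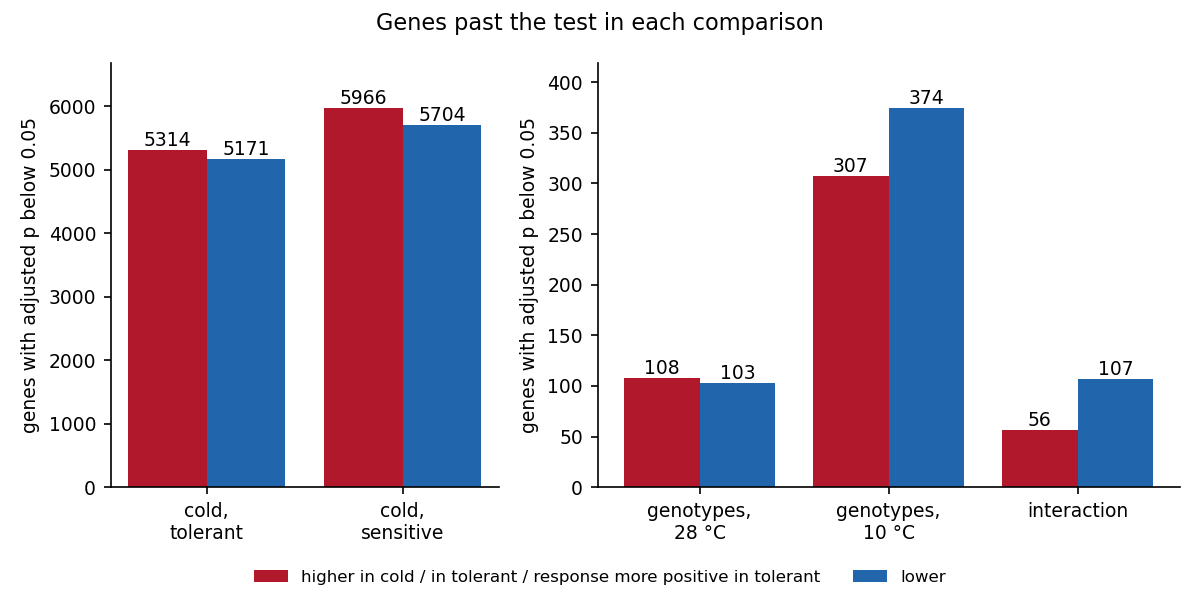
Genes past an adjusted p of 0.05 in each comparison, split by direction; bar height is the number of genes, and the left and right panels have separate axes. Cold changed 10485 genes in tolerant and 11670 in sensitive roots, while 211 genes differed between the lines at 28 °C, 681 at 10 °C, and 163 in their response to cold.

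In tolerant roots the cold raised all tested loci of the dehydrin and trehalose lists, while other lists moved in part or both ways. All 6 loci of the dehydrin and LEA list, proteins that accumulate in drying tissue and seeds, rose. The most abundant of them stood at 1764 normalised counts at 28 °C and 15462 at 10 °C, a log2 change of 3.13 ± 0.53 (SE) in the authors' deposited table. Another went from 18.3 to 2561 normalised counts, and 3 of the 6 lay under the floor of 1.22 at 28 °C and between 56.0 and 163 at 10 °C. Both trehalose loci rose, from 6.53 to 595 and from 10.2 to 73.1 normalised counts.

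Of 7 abscisic acid loci tested, 4 rose in tolerant roots, with log2 changes of 2.85 to 5.60 in the authors' deposited table. The CBF/DREB and cold regulator list, which holds transcription factors of the early cold response, had 3 of 9 tested loci rise and 0 fall, with log2 changes of 0.94 ± 0.33 and 2.38 ± 0.48 (SE) in the authors' deposited table for 2 of them. The third went from under the floor to 31.6 normalised counts. Of 9 circadian clock loci, 4 rose and 2 fell; the largest rise was from 517 to 19244 normalised counts, 5.22 ± 0.27 (SE) on the log2 scale in the authors' deposited table. Iron uptake and phytosiderophore loci, which serve the uptake of iron from soil, fell at 4 of 10, the largest fall being from 14715 to 380 normalised counts. Aquaporins, the water channels of membranes, fell at 3 of 4 loci, with log2 changes of −1.15 to −0.75 in the authors' deposited table. Of 3 catalase loci, 1 rose and 1 fell, of 3 nitrate transport loci 1 fell, and of 2 alcohol dehydrogenase loci 1 rose and 1 fell. Counts adjusted over the list alone were the same for each of these 10 lists.

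Among the lists added later, 7 of 12 JAZ loci, which encode repressors of jasmonate signalling, rose in tolerant roots and 0 fell. The wider aquaporin list had 3 of 13 rise and 5 fall (6 adjusted over the list alone), small heat shock proteins had 1 of 6 rise and 2 fall, and ammonium transporters had 1 of 3 fall. Photosynthesis loci, which mark shoot tissue, fell at 3 of 6; the largest fall was from 747 to 84.0 normalised counts. These counts were the same when adjusted over the list alone, apart from the aquaporin count given.

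In all, 10485 of 26199 genes tested passed in the authors' deposited table (40.0%), of which 5314 rose and 5171 fell (50.7% rose, 46.2% among changes of at least 2-fold and 61.9% above the median of mean expression); the median absolute log2 change among them was 1.66. LOC_Os03g04080 rose from 1 read over the group to 690 normalised counts, a ratio of 1697 (95% counting interval 305 to 67013). LOC_Os03g57640 rose at least 185-fold by its counting floor, from 0 reads to 226 normalised counts, with a deposited log2 change of 10.56 ± 2.43 (SE). LOC_Os01g25280 fell from 3433 normalised counts to 2 reads, a ratio of 3105 (860 to 25637), and LOC_Os09g19140 from 412 to 1 read, a ratio of 746 (134 to 29453). By Fisher's exact test over the fixed lists, the dehydrins rose more often than other genes (adjusted p = 0.000695), whereas abscisic acid loci (adjusted p = 0.175), clock loci (adjusted p = 0.291), cold regulators (adjusted p = 0.499) and falling iron loci (adjusted p = 0.291) did not pass. Among added lists, JAZ loci passed (adjusted p = 0.0339, Fisher's exact test) and shoot photosynthesis loci did not (adjusted p = 0.304), though camera called them lower in the cold with preset correlations of 0.01 (adjusted p = 0.0244) and 0.05 (0.0432) but not 0.2 (0.139). The JAZ call ended with calls at an adjusted p below 0.01 (0.226), above the median of mean expression (0.132) and in camera with a preset correlation of 0.2 (0.139). How reads shared by neighbouring copies were counted is not given in the sources used here, which bears on the dehydrin and iron loci that lie side by side.

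In sensitive roots the cold raised all tested dehydrin and trehalose loci and lowered most iron uptake loci. Of 10 iron uptake loci 9 fell and 0 rose, the largest fall being from 18405 to 183 normalised counts, −6.65 ± 0.83 (SE) on the log2 scale in the authors' deposited table. All 6 dehydrin and LEA loci rose; the most abundant went from 1288 to 16725 normalised counts, and another from 9.06 to 4248. Both trehalose loci rose, from 14.3 to 468 and from 10.8 to 71.1 normalised counts. Of 7 abscisic acid loci 5 rose and 1 fell, with log2 changes of 2.09 to 6.39 among the rises in the authors' deposited table.

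Cold regulators rose at 4 of 9 tested loci in sensitive roots and fell at 0, by log2 changes of 0.88 ± 0.33, 2.06 ± 0.43 and 2.61 ± 0.48 (SE) at 3 of them in the authors' deposited table; the fourth went from under the floor to 70.5 normalised counts. Of 9 clock loci 4 rose and 2 fell, and the largest rise was from 433 to 19328 normalised counts. Catalases had 1 rise and 1 fall among 3 loci, aquaporins 1 fall among 4, nitrate transport 1 fall among 3, and alcohol dehydrogenases 1 fall among 2. Adjusted over the list alone, 1 alcohol dehydrogenase locus also rose, and the counts of the other fixed lists were the same. Of the added lists, JAZ had 7 of 12 loci rise (8 adjusted over the list alone), the wider aquaporin list 5 of 13 rise and 2 fall, small heat shock proteins 1 of 6 rise (0 adjusted over the list alone) and 1 fall, shoot photosynthesis 1 of 6 rise and 1 fall, and ammonium transporters 0 of 3 either way. The median log2 change of the shoot photosynthesis loci was 0.08, opposite in sign to the camera statistic, which did not pass (adjusted p = 0.959).

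A total of 11670 of 26199 genes passed in sensitive roots in the authors' deposited table (44.5%), of which 5966 rose and 5704 fell (51.1% rose, 49.5% among changes of at least 2-fold and 55.6% above the median of mean expression), with a median absolute log2 change of 1.78. LOC_Os01g72900 rose from 3 reads to 2727 normalised counts, a ratio of 2125 (95% counting interval 727 to 10304), and LOC_Os03g57640 from 1 read to 711, a ratio of 1662 (298 to 65662). LOC_Os01g25280 fell at least 877-fold, from 1606 normalised counts to 0 reads, and LOC_Os10g31540 at least 589-fold, from 1079 to 0 reads. By Fisher's exact test over the fixed lists, rises of dehydrins (adjusted p = 0.000696) and abscisic acid loci (adjusted p = 0.0282) and falls of iron loci (adjusted p = 8.8e-05) were more frequent than in other genes. Rises of clock loci and of cold regulators did not pass the exact test (adjusted p = 0.217 for both), nor did those of JAZ loci (adjusted p = 0.0668). JAZ loci passed with calls at an adjusted p below 0.01 (0.0140) or of at least 2-fold (0.0149), and in camera with preset correlations of 0.01 (0.00200) and 0.05 (0.0129), but not with 0.2 (0.161) or above the median of mean expression (0.175). The camera test with a preset correlation of 0.2 ended the calls of abscisic acid and iron loci (adjusted p = 0.0746 for both), calls at an adjusted p below 0.01 also ended that of abscisic acid loci (0.0702), and the count fell to 7496 when only genes above the median of mean expression were tested.

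**Figure D2:**
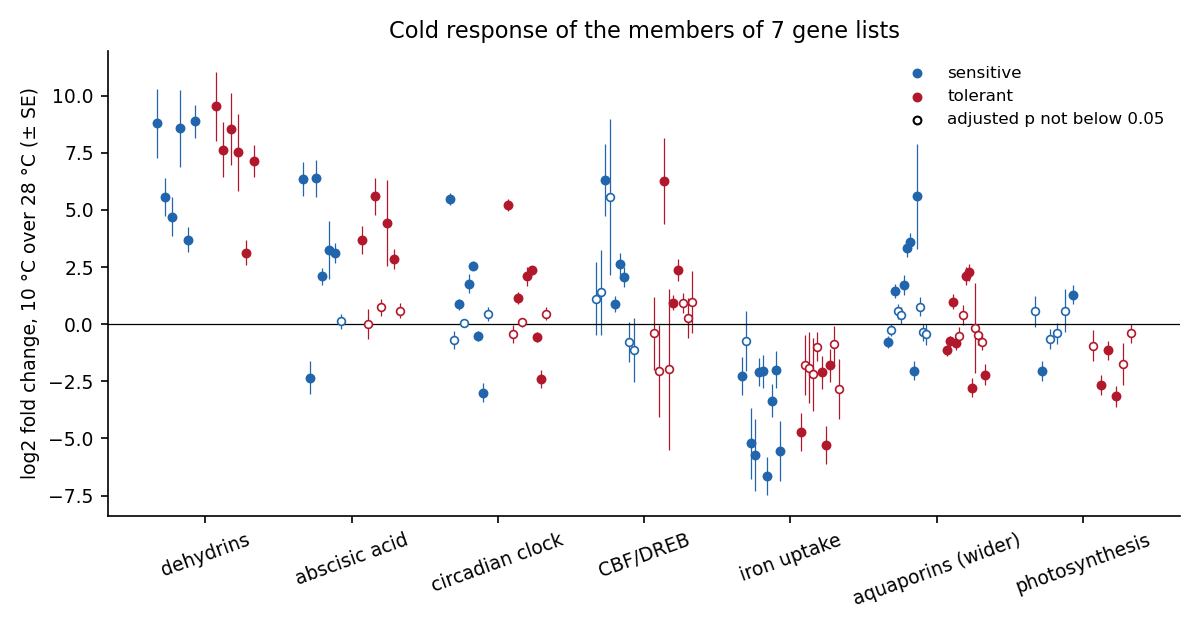
Log2 change from 28 °C to 10 °C, with its standard error from the authors' deposited tables, for each tested locus of 7 gene lists in sensitive (blue) and tolerant (red) roots; open points did not pass an adjusted p of 0.05. All 6 dehydrin loci lie above 0 in both lines, and all 10 iron uptake loci below it.

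Whether the lines differed in their response to cold was asked of the difference itself. Genes past this test were mostly ones with the smaller response in tolerant roots, 111 of 163 (68.1%). LOC_Os03g11650 went from 1820 to 195 normalised counts in sensitive roots and from 1201 to 957 in tolerant roots, and LOC_Os10g31630 from 983 to 12.1 and from 958 to 165; the differences in log2 change were 2.90 ± 0.43 and 3.80 ± 0.56 (SE). In the other direction, LOC_Os09g29490 went from 552 to 48.4 in tolerant roots and from 201 to 151 in sensitive roots, and LOC_Os07g14740 from 224 to 106 and from 82.6 to 281, with differences of −3.10 ± 0.50 and −2.84 ± 0.48 (SE). All 13 loci of the wider aquaporin list had the more negative response in tolerant roots, with a median difference of −1.24 on the log2 scale.

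Most of the cold response was shared by both lines: of 8370 genes called in both, 8360 went the same way, with 4330 rising where 1210.1 were expected from independent calls and 4030 falling where 1126 were expected, and 10 went opposite ways. Across 20132 genes with a mean of at least 20, Pearson's r between both responses was 0.899, where genes are not independent replicates. The genes that rose in both had median log2 changes of 1.57 in tolerant and 1.68 in sensitive roots, and those that fell in both −1.93 and −2.10. Of 26199 genes, 163 passed the derived Wald test, 56 with the more positive and 107 with the more negative response in tolerant roots, and 57 passed at an adjusted p below 0.01. The share with the more positive response was 34.4%, against 43.9% at an adjusted p below 0.01 and 46.3% above the median of mean expression. Of these 163, 71 rose in sensitive roots with a smaller rise or a fall in tolerant roots, 46 fell in sensitive roots with a smaller fall or a rise in tolerant roots, and 9 were called in opposite directions. Among the 55 tested loci of the fixed lists 0 passed the derived Wald test, with 7 at an unadjusted p below 0.05, so that the difference between 9 and 4 falling iron loci was not shown (camera, adjusted p = 0.295). Adjusted over the list alone, 3 abscisic acid loci and 1 aquaporin locus passed.

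The wider aquaporin list had 0 of 13 loci past the test over all genes and 2 adjusted over the list alone, and camera gave an adjusted p of 1.51e-07 with a preset correlation of 0.01 and 0.00373 with 0.2. Shoot photosynthesis loci moved the same way, more negative in tolerant roots at 6 of 6 loci, with a median difference of −1.59 (camera, adjusted p = 3.53e-05) and 1 locus past the test over all genes. Both lists were written after the data were seen. The wider aquaporin list shares loci with the fixed one, whose 4 loci all had the more negative response in tolerant roots. None of the 12 JAZ loci, 6 small heat shock loci or 3 ammonium transporter loci passed the derived Wald test, and 0 had an unadjusted p below 0.05.

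**Figure D3:**
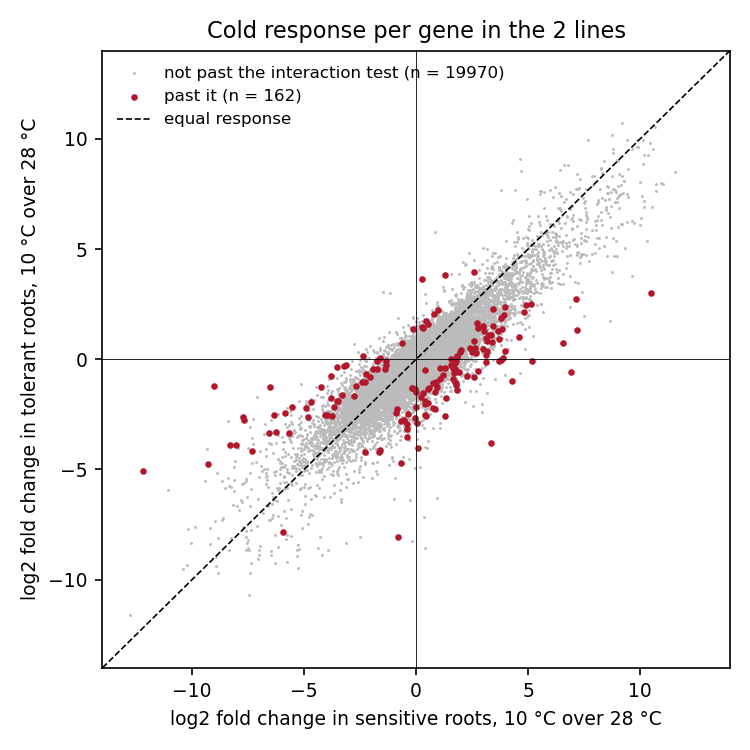
Log2 change from 28 °C to 10 °C of each gene with a mean of at least 20 normalised counts, in sensitive roots (x axis) and tolerant roots (y axis), with the line of equal response dashed; red points are 162 genes past the test of the difference and grey points the other 19970. Most genes lie near the line, and Pearson's r across genes was 0.899.

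At 28 °C the lines differed at few genes, and these lay close together on the chromosomes. In tolerant roots 108 genes were higher and 103 lower than in sensitive roots. LOC_Os04g02490 was at least 910.0-fold higher in tolerant roots, with 1168 normalised counts against 0 reads. LOC_Os09g39090 stood at 7961 normalised counts against 3 reads, a ratio of 6202 (95% counting interval 2122 to 30074). The deposited log2 difference of LOC_Os09g39090 was 12.53 ± 2.29 (SE), a wider spread than that of the counting interval. LOC_Os04g02070 stood at 1 read in tolerant roots against 564 normalised counts, a ratio of 1387 (249 to 54800), and LOC_Os04g02110 at 1 read against 433, a ratio of 1063 (191 to 42004). Chromosome 9 held 51 of the 211 genes among 1557 tested, 4.28 times the expected number, chromosome 11 held 40 (3.13 times) and chromosome 7 held 40 (2.48 times), while chromosome 3 held 1 of 3409 tested.

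The 211 genes passed among 27576 tested in the authors' deposited table, with a median absolute log2 difference of 3.23. Their spread over chromosomes departed from chance (permutation p = 1e-05, the smallest that 100000 shuffles can give). The same permutation test passed for every comparison, with p = 4e-05 in tolerant and 1e-05 in sensitive roots for the cold response and 0.00184 for the difference between responses, though no chromosome passed 1.07 times the expected number in either cold response. In 13 stretches of neighbouring loci, with 1015 tested loci or 3.68% of all, lay 108 of the 211 genes (51.2%). Chromosome 9 had 4 of these stretches, chromosome 11 had 3, chromosome 7 had 2, and chromosomes 1, 2, 4 and 10 had 1 each. Of 56 tested loci of the fixed lists, 1 passed, an alcohol dehydrogenase locus at 537 normalised counts in tolerant and 1655 in sensitive roots, −1.62 ± 0.45 (SE) on the log2 scale in the authors' deposited table. Adjusted over the list alone, 1 aquaporin locus was also higher in tolerant roots. Of 41 loci in the added lists 0 passed in the authors' deposited table made with DESeq2, with 1 at an unadjusted p below 0.05; the wider aquaporin list as a whole was higher in tolerant roots (camera, adjusted p = 2.4e-05 with a preset correlation of 0.01 and 0.0373 with 0.2). For dehydrins, the median log2 difference of 0.23 and the camera statistic had opposite signs, and camera did not pass (adjusted p = 0.903). The count became 95 above the median of mean expression and 801 when the statistics were rescaled by their robust spread.

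**Figure D4:**
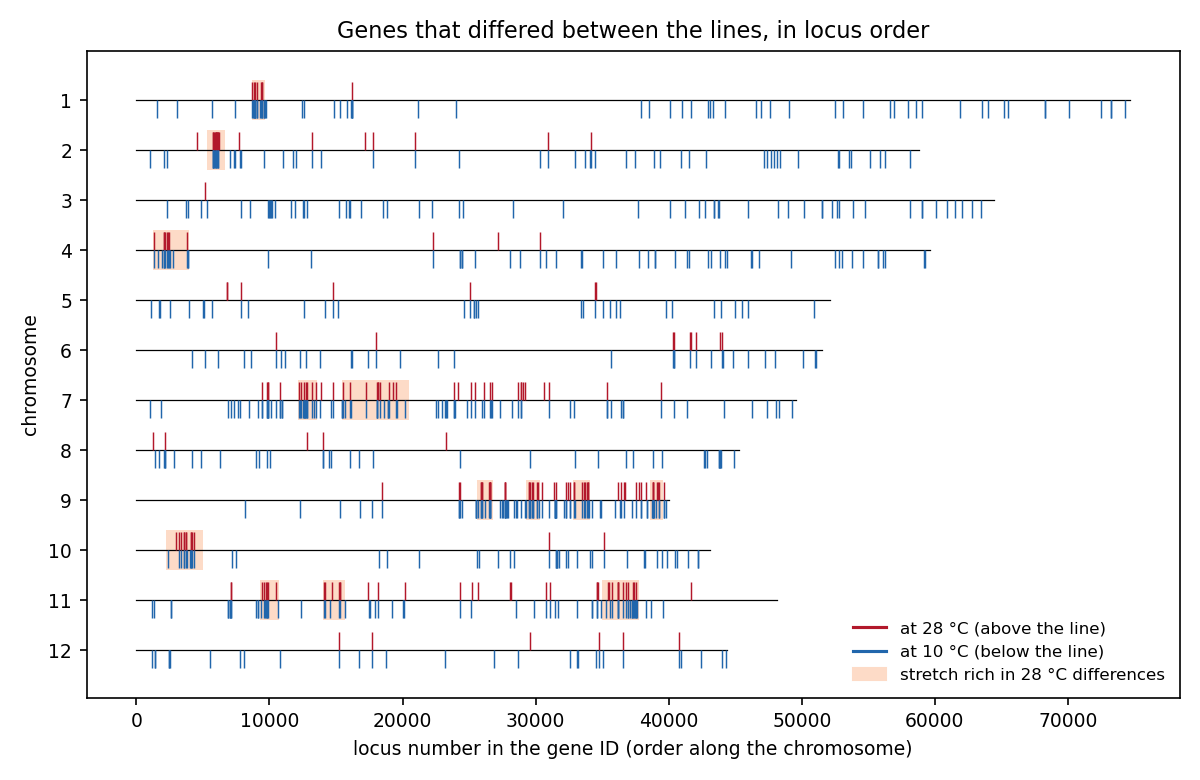
Positions of genes that differed between the lines, by locus number along the 12 chromosomes, at 28 °C (red, above the line) and at 10 °C (blue, below). Shaded are the 13 stretches rich in differences at 28 °C, which held 108 of the 211 genes.

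At 10 °C most genes of the 28 °C comparison differed again in the same direction. Of the 211 genes, 151 were called at both temperatures, 75 higher in tolerant roots at both where 1.41 were expected by chance, 72 lower at both where 1.64 were expected, and 4 in opposite directions. LOC_Os04g02490 was at least 195-fold and LOC_Os07g26100 at least 133-fold higher in tolerant roots, with 358 and 243 normalised counts against 0 reads. LOC_Os07g15440 was at least 425-fold and LOC_Os04g02110 at least 406-fold lower, with 704 and 673 normalised counts in sensitive roots against 0 reads in tolerant roots. LOC_Os07g15440 had a log2 difference of −11.75 ± 2.13 (SE) at 10 °C. It was not called at 28 °C, with −3.68 ± 1.58 (SE) and an adjusted p of 0.843 in the deposited Wald test. LOC_Os09g39090, called at 28 °C, did not pass at 10 °C (deposited Wald test, adjusted p = 0.563), with 20.9 normalised counts in tolerant roots against 3 reads. Shoot photosynthesis loci were lower in tolerant roots at 2 of 6, with log2 differences of −2.12 ± 0.46 and −1.62 ± 0.42 (SE) in the authors' deposited table.

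Of 23446 genes tested at 10 °C 681 passed in the authors' deposited table, 307 higher and 374 lower in tolerant roots, with a median absolute log2 difference of 1.84. Chromosome 9 held 94 of them (2.46 times the expected number), chromosome 7 held 97 (1.87 times) and chromosome 11 held 71 (1.84 times; permutation p = 1e-05, the smallest that 100000 shuffles can give). Of 53 tested loci of the fixed lists 0 passed in the authors' deposited table made with DESeq2, with 4 at an unadjusted p below 0.05. Adjusted over the list alone, 1 abscisic acid, 1 catalase and 1 alcohol dehydrogenase locus were lower in tolerant roots. The exact test of the shoot photosynthesis loci gave an adjusted p of 0.0292, and 1 of 12 loci of the wider aquaporin list was lower (camera, adjusted p = 0.00304 with a preset correlation of 0.01 and 0.124 with 0.2). JAZ, small heat shock and ammonium transporter loci had 0 of 11, 0 of 5 and 0 of 3 past the test in the authors' deposited table made with DESeq2, and 1, 0 and 0 at an unadjusted p below 0.05. The count of 681 became 330 above the median of mean expression, where the balance turned from 45.1% to 57.6% higher in tolerant roots, and 403 at an adjusted p below 0.01. It became 272 when the statistics were rescaled by their robust spread, below the 801 of 28 °C, so the order of both counts turned.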

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

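Of the tests in this part, the test of the difference between responses, the aquaporin and shoot photosynthesis lists, and the tests on mixed RNA and on scaling were chosen only after the result was seen. All results below stand here because a test of the difference between both lines' cold responses passed. That test called 163 genes. The tolerant minus sensitive log2 difference was 2.90 for LOC_Os03g11650, 3.80 for LOC_Os10g31630, −3.10 for LOC_Os09g29490 and −2.84 for LOC_Os07g14740. Of the lists, the wider aquaporin list passed with an adjusted p of 1.51e-07 and the shoot photosynthesis list with 3.53e-05 (camera, preset correlation 0.01), and both adjusted p-values were 0.00373 at a preset correlation of 0.2. The wider aquaporin list shares loci with the fixed one, whose 4 loci all had the more negative response in tolerant roots, so its result is not independent of that list. Whether shoot tissue stood in some root samples was not tested, nor whether it bears on the aquaporins.

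Among the 163 genes, 111 had the smaller response in tolerant roots. For genes that fell in both lines the median tolerant minus sensitive difference was 0.19 on the log2 scale, and for genes that rose in both it was −0.03. Control RNA mixed into the tolerant cold libraries could leave shifts of this small size, with median shares of 3.65% for genes that rose in both and 3.23% for genes that fell in both. Of 3599 abundant genes called lower in tolerant roots, 1.17% kept less than the lower share by more than 2 standard errors. This lay between the bounds first set, so that mixing stays open. An earlier form of this test, with a higher share and a bound widened after its result, was dropped. A further test, on rises past the test of the difference, was also dropped, since those genes were selected for a large difference. The shares were not taken from the 163 genes, whose median absolute difference was 2.29 on the log2 scale. An error of scaling would shift rises and falls alike, yet the medians of falls and rises lay 0.218 apart (0.191 to 0.250 with chromosomes resampled). For these shared genes, that argues against it as the whole cause. The gap restates the medians given above, and its interval leaves out the spread between replicates. A biological difference between the lines may remain, and no test here speaks for it.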

How the results depend on the processing

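Rescaling by the robust spread, the camera tests, other window sizes and the added lists were chosen after seeing the data. Of the values under alternatives, 21 of 28 counts stayed within 1.5 times, as did 2 of 2 overlaps (6443 and 6175), and 60 of 60 tests of named IDs, 43 of 54 of fixed lists, 37 of 46 of added lists and 2 of 2 of stretches kept their side of the threshold; 0 reversed. The named IDs were picked among called genes for large changes or low p-values. Their alternatives only repeated the adjustment of the same p-values over other sets of genes, so their outcome says little about processing. Counts above the median of mean expression were 7496 for sensitive roots in the cold, 95 at 28 °C and 330 at 10 °C, where fewer genes were tested. At an adjusted p below 0.01, 403 genes passed at 10 °C and 57 in the difference between responses, by the stricter threshold itself. With the robust spread, 801 passed at 28 °C and 272 at 10 °C, since the divisor was below 1 at 28 °C and above it at 10 °C. In tolerant roots the preset correlations of 0.01 and 0.05 gave adjusted p-values of 0.00498 and 0.0122 for abscisic acid loci, 0.00196 and 0.00795 for clock loci, and 0.0146 and 0.0359 for iron loci, all past the threshold where Fisher's exact test was not; so did 0.00470 and 0.0137 for clock loci in sensitive roots. With 0.2 none of these passed (0.0655, 0.0655 and 0.144 in tolerant roots, 0.0773 for clock loci in sensitive roots). In sensitive roots abscisic acid loci no longer passed with calls at an adjusted p below 0.01 (0.0702) or a preset correlation of 0.2 (0.0746), nor iron loci at 0.2 (0.0746). For the list tests the cause was not tested. No paired analysis was possible because values per library were not used here. For the same reason other size factors, other count tests, fits of 4 libraries, leaving out libraries, pseudocounts, fry and camera with an estimated correlation were not run. Depth limits the folds of genes with 0 to 3 reads in a group.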

Other observations

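Of the tests in this part, those on tandem copies, on neighbours moving together and on alleles were chosen only after the result was seen. Some genes were near absent in 1 line at both temperatures, with a level below 1 there and of at least 20 in the other line. There were 18 such genes near absent in sensitive roots, with the highest level in tolerant roots at 1168 normalised counts, and 13 near absent in tolerant roots, with the highest level in sensitive roots at 768.

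Of the 211 genes that differed between the lines at 28 °C, 108 lay in 13 stretches, and 4 explanations were weighed. Tandem copies that share reads could give pairs of neighbours, yet thinned calls 11 to 100 loci apart still formed 3.76 times the expected pairs. Neighbouring genes that move together in any comparison would cluster in the cold responses too: for the 211 strongest genes of each, pairs up to 100 loci apart were 1.00 and 0.990 times the expected number in tolerant and sensitive roots, against 5.04 at 28 °C, while adjacent pairs were 4.21 and 2.98 times, against 18.2. Reads of 1 line lost to distance from the reference would put a stretch's genes on 1 side; 72.2% (95% interval 62.8 to 80.4) lay in the majority direction, under the bound set beforehand for it as the whole cause but above the 58.3 to 69.4% of random directions, so for part of the genes it stays open. Different alleles in the stretches may fit: genes not called at 28 °C were called at 10 °C more often inside (odds ratio 4.49, 95% interval 3.42 to 5.89), though loss of reads gene by gene was not told apart from expression.

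More genes passed the test between the lines at 10 °C (681) than at 28 °C (211). Size factors were lower at 10 °C (0.679 to 0.991) than at 28 °C (1.10 to 1.25), so greater depth was not the cause. A shared spread for libraries of unequal spread could give the difference: the robust spread of the statistics was 1.21 at 10 °C and 0.675 at 28 °C. After rescaling by the spread outside the stretches, 290 genes passed at 10 °C and 857 at 28 °C, a ratio of 0.338. That rescaling takes most genes as equal between the lines. Broad true differences at 10 °C would widen the spread too and be divided away, so the ratio does not tell them apart from libraries of unequal spread. Which temperature held more true differences therefore stayed open.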
